A study of Cladocopium goreaui with 12 samples.

How the data were processed

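The series follows *Cladocopium goreaui*, a dinoflagellate alga that lives inside coral cells as a photosynthetic symbiont, in coral larvae exposed to their native algal symbionts. Larvae were sampled at 3, 12, 48 and 72 h, with 3 libraries at each time and 12 libraries in all. Per the labels' protocols, libraries were made with the TruSeq kit from total RNA. The protocols describe RNA from whole larvae, with no step that separates algal from larval RNA.

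The authors deposited FPKM values, mapped fragments scaled by transcript length and by the library's total, for assembled transcripts. The submitters' processing notes name Bowtie2, RSEM and edgeR, without versions or roles. The reference assembly is not given in the sources used here. Each table listed the same 183989 transcripts in the same order, grouped by their identifiers into 155375 gene components. Of these transcripts, 115249 were listed at 0 in all 12 libraries, 68740 were above 0 in at least 1 library, 14819 were above 0 in only 1 library and 2117 were above 0 in all 12. No pair of libraries held identical values. A further 3 columns carry names that match no sample of the series and were used in no step. The files do not pair the transcript identifiers with gene names, and no reference was used, so the gene lists chosen before the data were examined (by product name) could not be applied. For the same reason at most 4 identifiers are named. They are the 2 transcripts higher and the 2 lower at 72 h than at 3 h with the largest fitted change, among those past the threshold with a mean value of at least 5 and no overlap between the 3 values of each group.

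The number of mapped fragments per library was inferred from the deposited FPKM. In a library of N fragments, a transcript's FPKM is a whole multiple of a step set by N and by its effective length. The shallowest library gave N from the periodicity of its reciprocal values, and the others from the requirement that transcripts resolved in other libraries hold whole numbers of fragments. A value counted as whole within 0.1 of an integer, for transcripts with an effective length above 700. By that tolerance 20% of values would be whole at an arbitrary N. Here N was chosen for a high share of whole values, at least 0.75, so the shares reached describe the match and do not test it. Between 96.7% and 99.3% of the checked values were whole in 11 libraries, and 86.8% were in the deepest, the second replicate at 72 h. RSEM can divide a fragment among transcripts, so the totals are estimates of the fragments behind the listed values. The role of edgeR is not given, and any factor by which the deposited FPKM were scaled would be taken into N. For a resolved transcript of the median effective length, 911, 1 fragment was worth 9.14 FPKM in the shallowest library and 0.529 FPKM in the deepest.

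For tests across transcripts, FPKM was rescaled in each library to a common sum and divided by a median-of-ratios factor over the 2117 transcripts above 0 in all 12 libraries. These factors ran from 0.581 to 1.77. Transcripts with a mean of at least 1 over the 12 libraries were kept, which left 50964. FPKM is not a count, so no count model was used. Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3, in 1 fit of all 12 libraries with an intensity trend in the prior variance and no block. Log2 changes are on this scale, which understates the change of weakly expressed transcripts. Two-sided p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The comparisons were each later time against 3 h, the consecutive steps from 12 to 48 h and from 48 to 72 h, and a moderated F test over the 4 times. Single values per library were compared by exact permutation of all 369600 assignments of 12 libraries to 4 groups of 3, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Relations across the 12 libraries used 100000 permutations. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these libraries.

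The fit was tested on simulated data drawn at the inferred depths with 250 planted changes of each kind between 3 and 72 h, over 5 draws. In a median of 51975 tested transcripts it recovered 40.8% of 16-fold increases, 3.2% of 4-fold increases, 3.6% of 16-fold decreases and 0% of 4-fold decreases. A separate simulation drew 20 data sets from 1 unchanged profile at the same depths, with no change between times, and passed them through the same fit.

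The alternatives tried were another pseudocount (0.1 or 5), no filter, a filter at a mean of 5, only transcripts above 0 in all 12 libraries, the sum scaling alone, FPKM as deposited, quantile normalization, the replicate number as a block, only the 2 groups compared, array weights, no intensity trend and leaving out each library. Summing over gene components, weighting by inferred fragments and leaving out the deepest and shallowest libraries were added after the data had been seen.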

Results

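Transcription of the dinoflagellate symbiont *Cladocopium goreaui* (ITS2 type C1) was measured by RNA sequencing of coral larvae exposed to their native algae, at 3, 12, 48 and 72 h, with 3 libraries per time. The series asks how symbiont transcription changes over the first 72 h of colonisation, and its title speaks of repression. The values are FPKM per assembled transcript. The fragments inferred from these values differed widely between libraries. At 3 h the libraries held 172000, 271000 and 120000 fragments. At 12 h they held 329000, 262000 and 197000. At 48 h they held 471000, 318000 and 406000, and at 72 h 885000, 2075000 and 365000. The deepest library thus held 17.3 times as many fragments as the shallowest, and depth was lowest on average at 3 h and highest at 72 h.

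The number of transcripts detected above 0 FPKM increased with time. It averaged 16132 ± 7994 (SD, n = 3) at 3 h, 22722 ± 6368 (SD, n = 3) at 12 h, 30611 ± 3993 (SD, n = 3) at 48 h and 42460 ± 12044 (SD, n = 3) at 72 h, a ratio of 2.63 between the last and the first time. The 4 times differed by more than the spread between replicates (exact permutation test, p = 0.0118). Single libraries ran from 8360 transcripts, in the third replicate at 3 h, to 54124, in the second replicate at 72 h. Transcripts above 0 in all 3 libraries of a time numbered 3713 at 3 h, 8802 at 12 h, 16084 at 48 h and 23627 at 72 h. Those above 0 in all 3 libraries of a time and listed at 0 in every library of the other times numbered 0, 3, 19 and 473 in the same order.

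**Figure D1:**
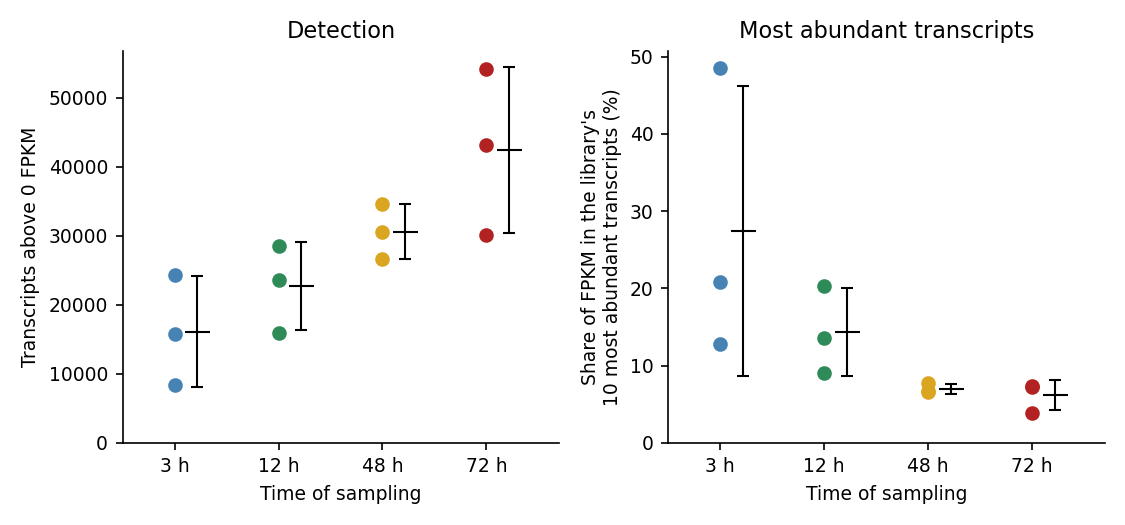
Transcripts above 0 FPKM (left) and the percent of all FPKM held by each library's 10 most abundant transcripts (right), by time of sampling. Each point is a library and the offset bars are the mean and SD of 3 libraries; mean detection goes from 16132 at 3 h to 42460 at 72 h while the mean share goes from 27.4% to 6.15%.

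Detection went with depth across the 12 libraries. Pearson's r between log2 transcripts detected and log2 inferred fragments was 0.916 (permutation p = 0.00015, adjusted p = 0.00018 over 6 tests) and Spearman's rho was 1 (permutation p = 1e-05, the smallest these permutations can give, adjusted p = 2e-05). Without the 2 libraries farthest from the median depth r was 0.976. Within the times, where depth also varied, the library order by transcripts detected was the order by fragments in 4 of 4 groups. The within-group slope of log2 detected on log2 fragments was 0.558 ± 0.150 (SE, exact permutation within groups, p = 0.00154). Once this slope was removed, the 4 times did not differ past the threshold in detection (exact permutation test, p = 0.423).

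**Figure D2:**
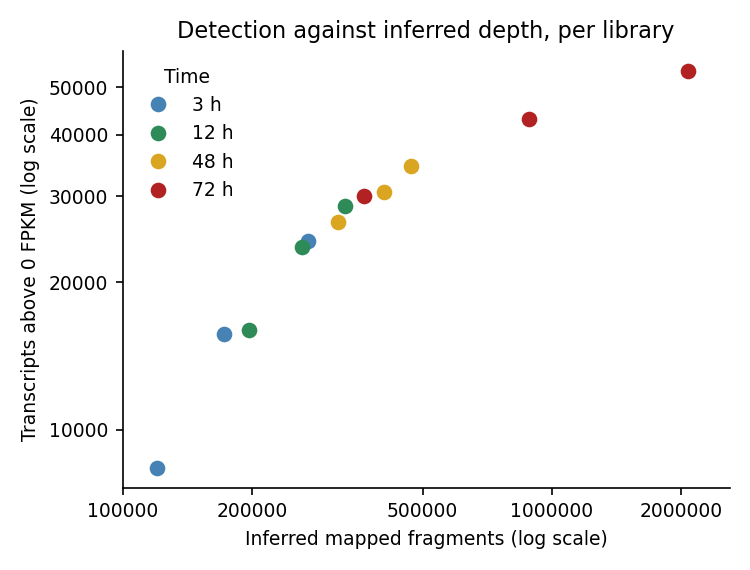
Transcripts above 0 FPKM against inferred mapped fragments, both on log axes, with 1 point per library coloured by time. The 12 libraries follow 1 rising curve, with the 3 h libraries at 120000 to 271000 fragments and the 72 h libraries at 365000 to 2075000.

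A small set of abundant transcripts took a larger share of the early libraries. The 10 most abundant transcripts of each library held 27.4% ± 18.8 (SD, n = 3) of all FPKM at 3 h, 14.3% ± 5.69 (SD, n = 3) at 12 h, 7.00% ± 0.641 (SD, n = 3) at 48 h and 6.15% ± 1.94 (SD, n = 3) at 72 h. The times differed (exact permutation test, p = 0.0210), by -21.2 percentage points between 72 h and 3 h. This call was lost in the exact permutation test without any 1 library of 48 h or 72 h, without the first or the second of 12 h or without the third of 3 h (p from 0.0571 to 0.0666). The third replicate at 3 h had a share of 48.5%, and the difference without it was -10.7 points. Across the 12 libraries r between log2 of this share and log2 fragments was -0.863 (permutation p = 0.00044, adjusted p = 0.00044) and rho was -0.951 (permutation p = 3e-05, adjusted p = 4.5e-05), with r of -0.980 without the 2 libraries farthest from the median depth. The 10 transcripts with the highest mean at 3 h were then followed through the series. They held 26.8% ± 19.4 (SD, n = 3) at 3 h, 13.3% ± 5.95 (SD, n = 3) at 12 h, 4.89% ± 0.987 (SD, n = 3) at 48 h and 3.41% ± 2.33 (SD, n = 3) at 72 h. They were picked at 3 h, so their higher level there is favoured by the choice and was not tested. Between 12, 48 and 72 h, which had no part in the choice, their share differed (exact permutation test, p = 0.0214). Once the slope of log2 share on log2 fragments within these times was removed, it did not differ past the threshold (exact permutation test, p = 0.114). The 2 named lower transcripts given for 72 h are among the 10.

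Libraries of a time resembled each other only slightly more than libraries of different times. The mean Pearson r of log2 values across transcripts, which are not independent replicates, was 0.323 within times and 0.297 between times (difference 0.0261, exact permutation test, p = 0.00455). This call was lost without the second or the third replicate at 48 h (exact permutation p = 0.0701 and 0.0511) and without the first, the second or the third at 72 h (exact permutation p = 0.306, 0.174 and 0.159). Without the first at 72 h the difference was 0.00397. Mean r between replicates was 0.219 at 3 h, 0.289 at 12 h, 0.351 at 48 h and 0.433 at 72 h. The library with the highest r was the deepest one, the second replicate at 72 h, for 10 of the other libraries, and only the 3 libraries of 72 h were closest to one of their own time.

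The comparison of 12 h with 3 h asks which transcripts changed in the first hours after exposure. Of 50964 transcripts tested by limma, 41 were higher at 12 h and 4 were lower. All 41 were listed at 0 in the 3 libraries of 3 h and above 0 in the 3 of 12 h, with a median FPKM of 107 at 12 h, and all 4 lower ones were listed at 0 at 12 h. Their 45 are 0.0883% of the transcripts tested, and 3307 had an unadjusted p under 0.05. The count moved when single libraries were left out, mostly upward in the largest shifts. It was 209 without the second replicate at 3 h, 96 without the third at 12 h and at its lowest 31, without the second at 72 h. The second replicate at 3 h was the deepest of its time and the third at 12 h the shallowest, so leaving out either widened the gap in depth. Leaving out the third at 3 h or the first at 12 h narrowed that gap and gave 63 and 37 calls. Whether depth set these shifts was not tested. The lower calls moved as well. They numbered 23 (186 higher) without the second replicate at 3 h, 20 (43 higher) without the third at 3 h and 0 (37 higher) without the first at 12 h.

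By 48 h, limma called 59 transcripts higher and 3 lower than at 3 h. Again all 59 were listed at 0 in every 3 h library, and their median at 48 h was 97.2 FPKM. Of the 41 transcripts higher at 12 h, 29 were also called higher at 48 h. Both lists rest on the same 3 h libraries, and unchanged groups simulated at the inferred depths shared a median of 38.5, with draws from 26 to 49. Between 12 and 48 h themselves, 17 transcripts were higher and 3 lower, and the 17 were all among the 59 called against 3 h. The count against 3 h was 229 without the second replicate at 3 h, 118 without the third at 12 h and 101 without the second at 48 h. For 12 against 48 h it was 62 without the third replicate at 48 h, 50 without the third at 72 h, 44 without the first at 48 h, 42 and 34 without the third and the second at 12 h, and 39 and 34 without the second and the third at 3 h. Without the third replicate at 12 h the balance turned, with 16 transcripts higher and 26 lower at 48 h.

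The comparison of 72 h with 3 h spans the whole series and gave the most calls of the 5 pairwise comparisons, 164 higher and 2 lower. Data simulated from 1 unchanged profile at the inferred depths gave medians of 160.5 higher and 1 lower. With planted changes the fit recovered 40.8% of 16-fold increases and 3.6% of 16-fold decreases. The balance of calls therefore cannot show that few transcripts fell. All 164 were listed at 0 in every library of 3 h and above 0 in every library of 72 h, with a median of 73.8 FPKM. Among all tested transcripts, 4721 were listed at 0 in the 3 libraries of 3 h and above 0 in the 3 of 72 h, and 26 had the opposite pattern. The median log2 change of all tested transcripts was 0.97 (0.64 in the data simulated from 1 unchanged profile at the inferred depths), and 0.09 after quantile normalization, which called 98 higher and 2 lower. The count was 797 without the third replicate at 72 h, 335 without the second at 3 h and 252 without the second at 72 h. From 48 to 72 h, 88 transcripts were higher and 3 lower, and all 88 were among the 164. That count was 678 without the third replicate at 72 h and 211 without the second. Without the first, the second or the third replicate at 48 h, 19, 19 and 32 transcripts were lower and 55, 45 and 78 higher.

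The files give no gene names, so the transcripts with the largest fitted changes are known by identifier only. TR64073|c0_g4_i1 was listed at 0 in the 6 libraries of 3 and 12 h. It reached 163, 267 and 810 FPKM in the libraries of 48 h and 1636, 267 and 742 FPKM in those of 72 h (limma, adjusted p = 0.00216 for 72 h against 3 h). TR64241|c0_g15_i1 was listed at 0 at 3 h and in 1 library of 12 h, where the other libraries had 247 and 195 FPKM. It stood at 444, 345 and 350 FPKM at 48 h and at 588, 386 and 953 FPKM at 72 h (limma, adjusted p = 0.0351). Both lower transcripts carry the same component prefix, TR34407, so reads may be shared between them. TR34407|c0_g3_i1 had 991, 1028 and 13414 FPKM at 3 h and was listed at 0, 28.3 and 0 at 72 h. Its log2 change was -10.28 ± 1.33 (SE, n = 3, limma, adjusted p = 0.00487). The size depended on the pseudocount, with -12.5 at 0.1 and -8.65 at 5, and ran from -11.7 to -8.93 with 1 library left out. TR34407|c0_g2_i1 had 6061, 1382 and 11396 FPKM at 3 h and 166, 21.3 and 0 at 72 h, a log2 change of -8.97 ± 1.51 (SE, n = 3, limma, adjusted p = 0.0201). With 1 library left out this change ran from -10.7 to -7.11. The TR34407|c0_g3_i1 transcript was still at 309, 1007 and 753 FPKM at 48 h, and its step from 48 to 72 h passed the threshold (limma, adjusted p = 0.0330). Over the alternative settings, the limma adjusted p for 72 h against 3 h ran from 0.000626 to 0.0215 for TR64073|c0_g4_i1, from 0.0141 to 0.428 for TR64241|c0_g15_i1, from 0.00163 to 0.149 for TR34407|c0_g3_i1 and from 0.00859 to 0.191 for TR34407|c0_g2_i1. The call of TR64241|c0_g15_i1 was lost without any 1 library of 3 h or 72 h or without the first or the second of 48 h (limma, adjusted p from 0.0519 to 0.131). That of TR34407|c0_g2_i1 was lost without the first or the third replicate at 3 h or the second at 72 h (limma, adjusted p from 0.0522 to 0.126).

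**Figure D3:**
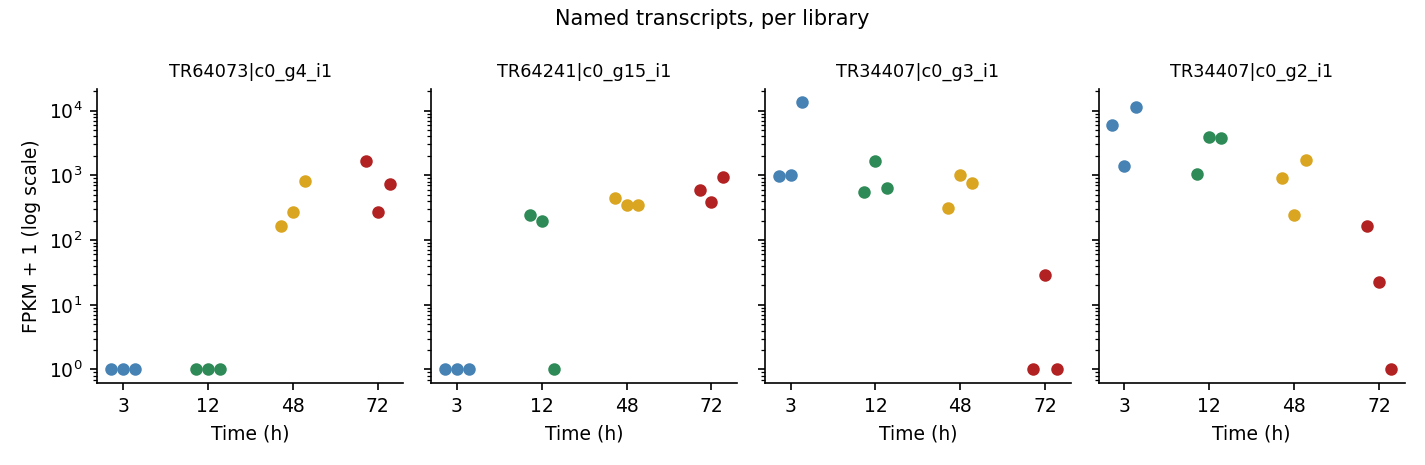
FPKM + 1 on a log axis for the 4 named transcripts in each of the 12 libraries, by time in hours. Points at the bottom of an axis are libraries in which the transcript is listed at 0, such as the 6 libraries of 3 and 12 h for TR64073|c0_g4_i1.

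The F test over the 4 times called 187 transcripts. Their highest mean was at 72 h in 102, at 48 h in 41, at 12 h in 38 and at 3 h in 6, and their lowest mean was at 3 h in 180. The count was 647 without the third replicate at 72 h, and 1.85 times as high without the second at 3 h. The comparisons of 48 h and 72 h with 3 h shared 48 higher transcripts, where independent lists would share 0.190, and no lower ones. They shared 193 without the second replicate at 3 h, 88 without the third at 12 h and 77 without the second at 12 h. Unchanged groups simulated at the inferred depths against the same 3 h libraries shared a median of 57 and at most 72, so the 48 are no more than unchanged groups gave. The covariance of the log2 changes was 1.39 against a simulated median of 1.26 and a simulated maximum of 1.29. Their correlation was 0.606 against a simulated median of 0.602 and a simulated maximum of 0.608. The 3 libraries of 3 h are too few to split, so what the shared baseline adds to the measured overlap could not be taken out.

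The calls were set beside data simulated from 1 unchanged profile at the inferred depths. The simulated medians were 72.5 calls for 12 h against 3 h, 78 for 48 h against 3 h, 161.5 for 72 h against 3 h, 36 for 48 h against 12 h, 83 for 72 h against 48 h and 197 over time. All 6 measured counts lay within the simulated ranges, but some only at the low end. For 12 h against 3 h, 45 were measured with draws from 44 to 108. For 48 h against 3 h, 62 were measured with draws from 60 to 101, and for 48 h against 12 h, 20 with draws from 20 to 63. The other counts lay nearer the simulated medians. The profile is an assumed one, which listed 23614 transcripts at 3 h on average where 16132 were measured. The measured median log2 change over all tested transcripts lay within the simulated range for 12 h against 3 h, at 0, and above it in the other 4 of the 5 pairwise comparisons. It was 0.62 with 0.25 simulated for 48 h against 3 h, 0.97 with 0.64 for 72 h against 3 h, 0.11 with 0.01 for 48 h against 12 h and 0.17 with 0.13 for 72 h against 48 h.

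**Figure D4:**
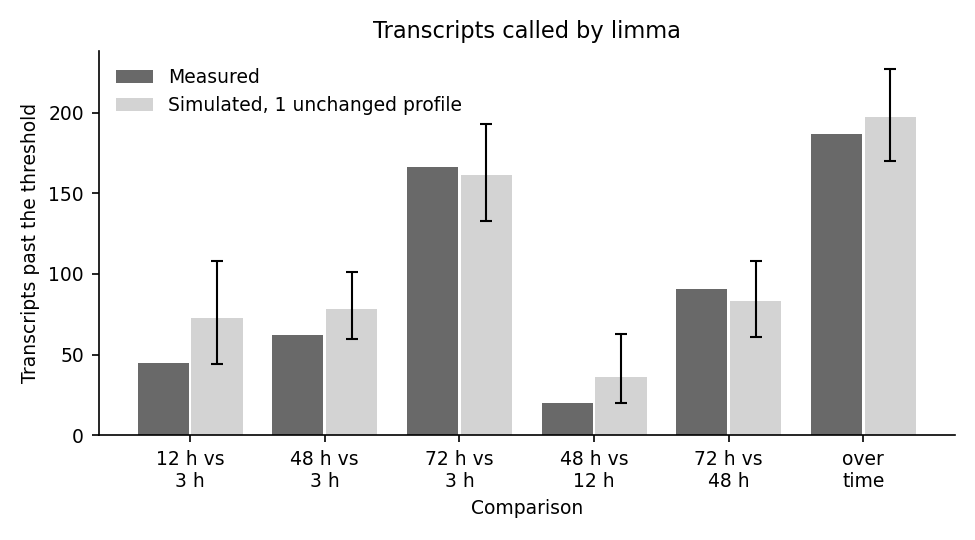
Number of transcripts past the limma threshold in each comparison, as measured (dark bars) and in 20 simulated data sets of 1 unchanged profile at the inferred depths (light bars, median, with error bars from the lowest to the highest draw). For 72 h against 3 h the measured count is 166 and the simulated median 161.5, with draws from 133 to 193.

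Transcripts detected in every library allow a comparison that does not start from 0, though not one free of depth. In the 2117 transcripts above 0 in all 12 libraries, limma called 12 between 72 h and 3 h, of which 11 were lower and 1 was higher at 72 h. The 11 had a median log2 change of -3.42, and 5 of them belong to the 10 transcripts most abundant at 3 h. Most of these calls went with depth too. Within the times, log2(FPKM + 1) of 9 of the 11 had a negative slope on log2 fragments, 8 of them with an unadjusted exact permutation p under 0.05. The others had positive slopes, of 0.456 ± 0.0864 (SE, unadjusted exact permutation p = 0.0116) and 0.689 ± 0.324 (SE, unadjusted exact permutation p = 0.0779). The mean over the 11 had a slope of -1.03 ± 0.150 (SE, exact permutation within groups, p = 0.00231). The scaling factors were set on these 2117 transcripts, which holds their median change near 0, so the changes are relative to that median. On simulated data for 72 h against 3 h with a median of 6828 such transcripts, the fit recovered 52.4% of 4-fold and 76.4% of 16-fold increases. It recovered 20.8% of 4-fold and 17.2% of 16-fold decreases, of which 172 and 51 of 250 stayed in the set. No transcript of this set was called by limma at 12 h or 48 h against 3 h, from 12 to 48 h or from 48 to 72 h, where 180, 240, 139 and 50 had an unadjusted p under 0.05. The F test over time called 5.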

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

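The weighting by inferred fragments, the sums over gene components and the fit without the deepest and shallowest libraries were chosen after the data had been seen. Counts of calls moved with most settings, and the cause was not tested except where named. The comparisons are in the order 12 h, 48 h and 72 h against 3 h, 48 h against 12 h, 72 h against 48 h and over time. With the 2117 transcripts above 0 in all 12 libraries, where no call can start from 0, there were 0, 0, 12, 0, 0 and 5 calls by limma. Quantile normalization gave 28, 34, 100, 10, 59 and 116. A pseudocount of 5 gave 9, 31, 90 and 9 calls in the first 4 and 114 over time. A pseudocount of 0.1 gave 109 and 102 in the first 2 and 0 for 72 h against 48 h. A filter at a mean of 5 gave 90 for 12 h against 3 h and 52 for 72 h against 48 h. No filter gave 60 for 72 h against 48 h. Without the intensity trend 12 h against 3 h had 71 calls. Weights by fragments gave 16, 36 and 75 in the first 3. Fits of only the 2 groups gave 208, 650, 82 and 10 for 48 h and 72 h against 3 h, 48 h against 12 h and 72 h against 48 h. Without the 2 deepest and the shallowest libraries, 72 h against 3 h had 1469 calls, with a lone 72 h library assumed to vary like the other groups. The calls shared by 48 h and 72 h against 3 h were 92 with a pseudocount of 0.1 and 28 with quantile normalization. Sums over gene components, the sum scaling alone, FPKM as deposited and array weights kept every count of calls within 1.5 times.

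No pairing of the libraries by replicate number showed in the values, but with 3 libraries per time this check could not exclude one. Deviations from the group means of same-numbered libraries correlated at -0.0184 to 0.0273, against -0.0341 to 0.0386 for other pairs, and 4 of 12 libraries correlated best with their own number. With the number as a block the counts were 24, 31, 104, 8, 44 and 104.

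Leaving out each library in turn gave 31 to 209 calls for 12 h against 3 h, 52 to 229 for 48 h, 113 to 797 for 72 h, 21 to 62 for 48 h against 12 h, 64 to 678 for 72 h against 48 h and 147 to 647 over time. It gave 37 to 193 shared calls. The highest counts came without the second replicate at 3 h (12 h and 48 h against 3 h, shared calls), the third at 72 h (72 h against 3 h and 48 h, over time) and the third at 48 h (48 h against 12 h). The ratio of detection ran from 2.12 to 3.53 and kept its side of the threshold each time. The difference in the top 10 share ran from -28.5 to -10.7 points and passed its threshold only without the replicates numbered 1 or 2 at 3 h or 3 at 12 h. The similarity difference ran from 0.00397 to 0.0472 and lost its threshold without the replicates numbered 2 or 3 at 48 h or any at 72 h. The named transcripts kept their direction in every setting that gave them a value, which the sums over gene components and the set above 0 in all 12 libraries did not. For 48 h against 12 h the balance turned without replicate 3 at 12 h, to 16 higher and 26 lower. The gene list tests and their alternatives were not run, since the identifiers have no names here. In simulated data for 72 h against 3 h, the fit of all tested transcripts recovered 3.2% of 4-fold increases and 0% of 4-fold decreases, and that of transcripts above 0 in all 12 libraries 52.4% and 20.8%.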

Other observations

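The tests of depth, of background and of change over time, and the reading of the other splits of the libraries, were set out after the results were seen.

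The 10 transcripts most abundant at 3 h held 26.8% of all FPKM there and 3.41% at 72 h, a fall that their choice at 3 h favours. Within 12, 48 and 72 h, which had no part in the choice, log2 of their share changed with log2 fragments at a slope of -1.13 ± 0.207 (SE, exact permutation within groups, p = 0.00926), near the -1 of a fixed amount of background RNA diluted by algal reads, while the other transcripts detected in all 12 libraries had a slope of 0.0473 ± 0.0323 (SE, p = 0.0972 in the same exact test), and of 0.0799 ± 0.0423 (SE, p = 0.0278 in the exact test) with 3 h included. The 10 did not move as 1 pool, however. Between 12 and 72 h the sum of log2(FPKM + 1) and log2 fragments changed by -6.32 to 0.78 among them. They moved apart between 12, 48 and 72 h (exact joint permutation test, p = 0.00714), which argues against a single fixed background as the source of all 10. The largest falls were those of the named TR34407|c0_g3_i1 (-6.32) and TR34407|c0_g2_i1 (-5.56). Both were listed at 0 in part of the 72 h libraries, so the added 1 bears on their size. Within these times their slopes on log2 fragments were 1.56 ± 0.757 and 1.58 ± 1.19 (SE), while every other member had a negative slope. On the same sum between 12 and 72 h, other members changed by -4.40, -2.31, -1.47 and -0.59, and the rest by 0.26 to 0.78. Of the members alone, 5 had an exact permutation p under 0.05 and 0 passed adjustment over the 10 (lowest adjusted p = 0.0833). A fixed background stays a candidate source for part of the summed share only, and how large a part was not tested. A fall in the algal cells stays open too, as 12, 48 and 72 h differed in the summed share with an exact permutation p of 0.114 once the slope was removed, and depth goes with time.

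The number of transcripts called higher at 72 h than at 3 h, 164, may be set by depth, since 1 unchanged profile sampled at the inferred depths gave a median of 160.5 higher calls (132 to 193 over 20 draws). Among the transcripts above 0 in all 12 libraries, only 1 was called higher at 72 h, but that set leaves out any transcript switched on after 3 h. Change over time in the algal cells and depth cannot be told apart for the 164. The simulated profile listed 23614 transcripts at 3 h on average where 16132 were measured, and its median log2 change between 3 and 72 h was 0.64 where 0.97 was measured, but the profile is an assumed one, which in the draws with planted changes put a median of 6828 transcripts above 0 in all 12 libraries where 2117 were measured, so these gaps leave open whether the algal profile changed.

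Detection followed depth within the times, with a slope of 0.558, and the difference between times left after removing it had an exact permutation p of 0.423. Set to the mean log2 fragments by that slope, detection had geometric means of 21652 at 3 h, 26408 at 12 h, 28701 at 48 h and 24898 at 72 h. Depth and a wider range of transcription at 72 h cannot be told apart here, because depth increased with time. The inferred fragments could themselves follow the amount of algal RNA per larva as colonisation proceeds, which these files do not measure and which was not tested.

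The 6 libraries of a comparison can be parted into 3 and 3 in only 10 ways, the real one included, too few for a share under 0.05. Counting the real split, at least as many calls came from 2 splits for 12 h against 3 h (45 real, highest other 236), from 2 for 48 h against 12 h (20 real, highest other 48) and from 3 for 72 h against 48 h (91 real, highest other 142). Only the real split, 1 of the 10, gave as many for 48 h against 3 h (62 real, highest other 25) and for 72 h against 3 h (166 real, highest other 14). In the 3 comparisons with a higher other split, that split parted the 3 libraries with the most inferred fragments from the 3 with the fewest, and for 48 h and 72 h against 3 h the real split did so. The 236 calls point to a structure of the libraries other than time. For the change over time, 5 of 100 drawn groupings of the 12 libraries, the real one included, gave at least the 187 calls (highest other 439), so chance cannot be excluded.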
